A study of Zea mays with 4 samples.

How the data were processed

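Upper leaves of maize (Zea mays) near-isogenic lines were measured by paired-end RNA sequencing of total RNA. Seedlings had been exposed to planthoppers carrying the virus and then grown in the field, per the labels' protocols. The 4 libraries were assigned to NIL-S (2) and NIL-R (2) from their titles, and table columns were assigned by the library code in each sample's description. All columns of both tables were mapped. Nothing in the labels says whether the replicates of a line came from separate plants, so p-values measure only the spread between these samples, which may be technical. A chi-square test over genes found that the replicates of each line differed far beyond sampling noise (chi-square per degree of freedom 33.0 in NIL-S and 41.1 in NIL-R). A technical spread could give this too, so the test does not show separate plants. Each library was counted as 1 sample.

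The authors deposited raw read counts per gene, not normalized. The submitters' processing notes name HISAT2 2.0.4, HTSeq 0.6.1 and DESeq 1.12.0 and the genome build B73 RefGen_v4, without giving their settings. Whether counting used strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The authors also deposited FPKM values. Each of the 33999 features with counts had 1 implied length that was whole within 0.01 bases in every library when the count was divided by the FPKM and the library's total, so the FPKM values are the same counts scaled by length and total, and those lengths are printed as the counted length. No row without a feature name was present.

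Totals were 21604790 to 25266942 counts per library. With 2 libraries per line, precision was limited by the spread between replicates (common biological coefficient of variation 0.230) more than by depth. edgeR 4.0.16 in R 4.3.3 was used for the comparison of NIL-R with NIL-S. Genes passed filterByExpr with a minimum count of 10, TMM normalization was applied, and glmQLFit with robust estimation and glmQLFTest gave two-sided p-values with Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are NIL-R over NIL-S. Standard errors were the fold change divided by the square root of the F statistic, and 95% intervals used its degrees of freedom. CPM values use TMM library sizes, except in the counts of separated and on or off features, which use the totals. Separated features were those with a mean of at least 1 CPM whose lines were at least 2-fold apart on log2(CPM + 0.5).

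The tests were tried on simulated data with the real library sizes and with means and dispersions estimated from the data. There were 200 changed genes, drawn from those with a mean of at least 50 counts, among 24691 (24349 passed the edgeR filter there). The scan of identifier numbers was also tried on simulated data: it called 2 of 100 random placements and found 100 of 100 planted runs. The placements were drawn as in the test itself and the planted runs were dense. This checked the code only, not weaker runs or neighbours that vary together. Alternatives were DESeq2 1.42.0, edgeR's likelihood ratio test, limma 3.58.1 (voom on counts, and trend on log2(FPKM + 1) with and without a mean FPKM of at least 1, and on log2(FPKM + 0.1) with it), RLE factors or totals in place of TMM, no filter, a minimum count of 50, an absolute log2 fold change of at least 1, a replicate block, and leaving out each library. Figures and the scan used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9.

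The edgeR test, the alternatives above, 38 gene lists and the rule for named genes were fixed before the data were examined. A table of NCBI gene symbols for the assembly Zm-B73-REFERENCE-NAM-5.0 matched 153 of the 49115 identifiers, all of them microRNA genes, and 0 of the annotated genes. None of the 38 lists (among them pathogenesis-related proteins, RNA silencing, hormone pathways, photosynthesis, cell wall, markers of other tissues and Rab GDP dissociation inhibitors) could therefore be formed, and the list tests and the gene carrying the ZmGDIα alleles were not analysed here. Positions were likewise not used, because the table's assembly is not the build of the files.

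The rule for named genes took the 2 unnamed features with the largest rise and the 2 with the largest fall among called genes with a mean of at least 5 CPM and lines that do not overlap. Because the quasi-likelihood test called none, the rule was applied to the DESeq2 calls, a step chosen after the data were seen. On or off features were to be named up to 3 per direction, and only those also taken by the first rule are named, since at most 2 identifiers without a gene name were to be printed per direction. The microRNA genes, the separated features, the identifier scan, a DESeq2 fit with a replicate block and the other splits of the libraries were also chosen after the data were seen. The replicate numbers were not taken as pairs, since the labels tie them to no shared batch or plant.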

Results

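RNA was sequenced from upper leaves of 2 near-isogenic maize lines, both exposed to rice black-streaked dwarf virus (RBSDV). RBSDV is a planthopper-borne virus that causes maize rough dwarf disease. NIL-S carries the ZmGDIα allele and is susceptible, and NIL-R carries the ZmGDIα-hel allele and is described as recessively resistant. Each line had 2 libraries labelled 16 days. No library from unexposed plants was analysed here, so the data compare exposed lines and do not measure a response to infection. The amount of virus in each library was not measured here, so the lines may differ in it. The deposited counts summed to 24418078 and 21604790 in the NIL-S libraries and to 25266942 and 25144835 in the NIL-R libraries. Of 49115 features in the table, 33999 had a count in at least 1 library. The 49115 were annotated genes (44146 features, 98.6% to 98.7% of each library's counts), features with a serial identifier in the authors' table (Novel01404 and the like, here called serial features; 2843), entries with an ENSRNA identifier (1798), entries with a GRMZM identifier (174) and microRNA genes (154).

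The comparison of NIL-R with NIL-S addressed which genes differ between the resistant and the susceptible line after exposure to the virus. No gene was higher and no gene was lower in NIL-R at an adjusted p under 0.05 among 24691 tested genes, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The smallest adjusted p was 0.162. Without adjustment, 976 genes had p under 0.05 (485 higher and 491 lower in NIL-R), where chance alone would give about 1235. That number became 2216 without NIL-R replicate 1 and 473 without NIL-R replicate 2, with 0 passing the adjustment in both. For 14208 of the 16286 genes with a mean of at least 5 counts per 1e6 counts (CPM), or 87.2%, the 95% interval of the log2 fold change lay inside a 2-fold change in either direction. In simulated counts for this comparison with changes placed in genes with a mean of at least 50 counts, the same test found 45 of 50 genes changed 4-fold, 48 of 50 changed 8-fold and 9 of 50 changed 2-fold. Changes of 2-fold were mostly not detectable there with 2 libraries per line, and the recovery for genes with fewer counts was not simulated. The simulation took the fitted dispersions as true and placed 200 changed genes, and the test called 127 genes, 24 of them unchanged. In the measured libraries the quasi-likelihood test called 0, also at large changes (log2 fold change -3.36, adjusted p 0.940 for Zm00001d039394). The recoveries therefore do not show that changes of 4-fold or more would have been found in the data.

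Other tests of the same counts did call genes. DESeq2 called 63 genes at an adjusted p under 0.05, of which 40 were higher and 23 lower in NIL-R. These were 50 annotated genes and 13 serial features. edgeR's likelihood ratio test called 85, of which 57 were among the DESeq2 calls, and limma-voom called 0, with 926 genes at an unadjusted p under 0.05. In a single simulated draw with 200 changed genes, unchanged genes made up 36.1% of the DESeq2 calls and 38.4% of the likelihood ratio calls. The shares were 18.9% for the quasi-likelihood test and 17.9% for limma-voom, so all lay above the 0.05 aimed for. DESeq2 found 21 of 50 genes changed 2-fold and 48 of 50 changed 4-fold there. The share of false calls among the 63 cannot be read from this draw. Splitting the 4 libraries by replicate number instead of by line gave 140 DESeq2 calls, and the remaining split, NIL-S replicate 1 and NIL-R replicate 2 against the other two, gave 70. The quasi-likelihood test called 0 in each of the 3 splits.

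The naming rule was applied to the DESeq2 calls after the data were seen. The pair it took with the largest rise was on in NIL-R and off or nearly off in NIL-S. The annotated gene Zm00001d021770 (4306 bases of counted length) had 0 counts in both NIL-S libraries, and 317 and 834 counts in the NIL-R libraries, a mean of 23.5 ± 15.4 CPM (SD, n = 2). It was at least 350.3-fold higher in NIL-R when NIL-S was set to 3 counts over both libraries. The exact (Clopper-Pearson) 95% counting interval of its ratio began lower, at 284. Novel01404 (4681 bases) had 1 and 0 counts in NIL-S against 464 and 1089 in NIL-R, a ratio of 1418 with an exact (Clopper-Pearson) 95% counting interval of 254 to 56035. Counting intervals here cover counting error only. By edgeR's quasi-likelihood test the adjusted p was 0.940 for Zm00001d021770 and 0.529 for Novel01404, and DESeq2 gave 9.2e-07 and 3.9e-09. Over all alternatives run, limma included, it ranged from 2.0e-17 to 0.965 for Zm00001d021770 and from 4.1e-22 to 0.947 for Novel01404. In the other direction, Zm00001d039394 had 39.7 ± 5.0 CPM in NIL-S and 3.9 ± 2.9 in NIL-R (SD, n = 2 each), a log2 fold change of -3.36 with a standard error of 0.60. Zm00001d028718 had 12.2 ± 2.2 CPM in NIL-S and 1.3 ± 0.85 in NIL-R (SD, n = 2 each), a log2 fold change of -3.26 with a standard error of 0.51. Both had an adjusted p of 0.940 by edgeR's quasi-likelihood test, and DESeq2 gave 1.4e-08 and 1.4e-07. Over the alternatives, limma included, the adjusted p ranged from 1.6e-15 to 0.965 for Zm00001d039394 and from 1.4e-07 to 0.956 for Zm00001d028718. Without NIL-R replicate 1 and without NIL-R replicate 2, the log2 fold change was -4.45 and -2.75 for Zm00001d039394 and -4.20 and -2.71 for Zm00001d028718. The source tables do not pair these identifiers with gene names. The gene with the smallest p, an annotated gene singled out after its values were seen, had 66.6 ± 6.0 CPM in NIL-S and 15.5 ± 0.97 in NIL-R (SD, n = 2 each), a log2 fold change of -2.11 with a standard error of 0.13. Its adjusted p was 0.162 by edgeR's quasi-likelihood test, and DESeq2 called it.

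Features off in one line and well expressed in the other were rare. Counting features with at most 3 counts over both libraries of one line and a mean of at least 5 CPM in the other gave 3 that were on in NIL-R and 0 that were on in NIL-S. The 2 other splits of the libraries gave 3 and 4 such features. At a mean of at least 1 CPM, 13 features were on in NIL-R and 11 in NIL-S. The split by replicate number gave 19 and 2 on its sides, and the remaining split gave 16 and 2. In both, the larger number was on the side that held NIL-S replicate 2. A mean can reach the cut-off through 1 library alone, so these counts do not tell a difference between sides from 1 divergent library.

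Serial features were more often separated between the lines than other features. Of 21847 features with a mean of at least 1 CPM, 70 had both libraries of one line at least 2-fold above both libraries of the other (40 higher and 30 lower in NIL-R). They included 12 of 1190 serial features (1.0%) and 58 of the others (0.28%), an odds ratio of 3.62 (Fisher's exact test, two-sided p = 3.7e-04, across features, which are not independent replicates). How the serial features were defined was not examined here. The test therefore cannot tell a property of these features from the way the class was formed. The split by replicate number separated 84 features, of which 1 was a serial feature, and the remaining split separated 47, of which 0 were; chance alone gives the 3 splits equal numbers on average. The 70 separated features became 29 at a mean of at least 5 CPM, and 453, 262, 428 and 122 without NIL-S replicate 1, NIL-S replicate 2, NIL-R replicate 1 and NIL-R replicate 2, since fewer libraries then have to separate. The share of all counts in serial features was 1.30% ± 0.094 in NIL-S and 1.31% ± 0.041 in NIL-R (SD, n = 2 each), a difference smaller than the spread between replicates.

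**Figure D1:**
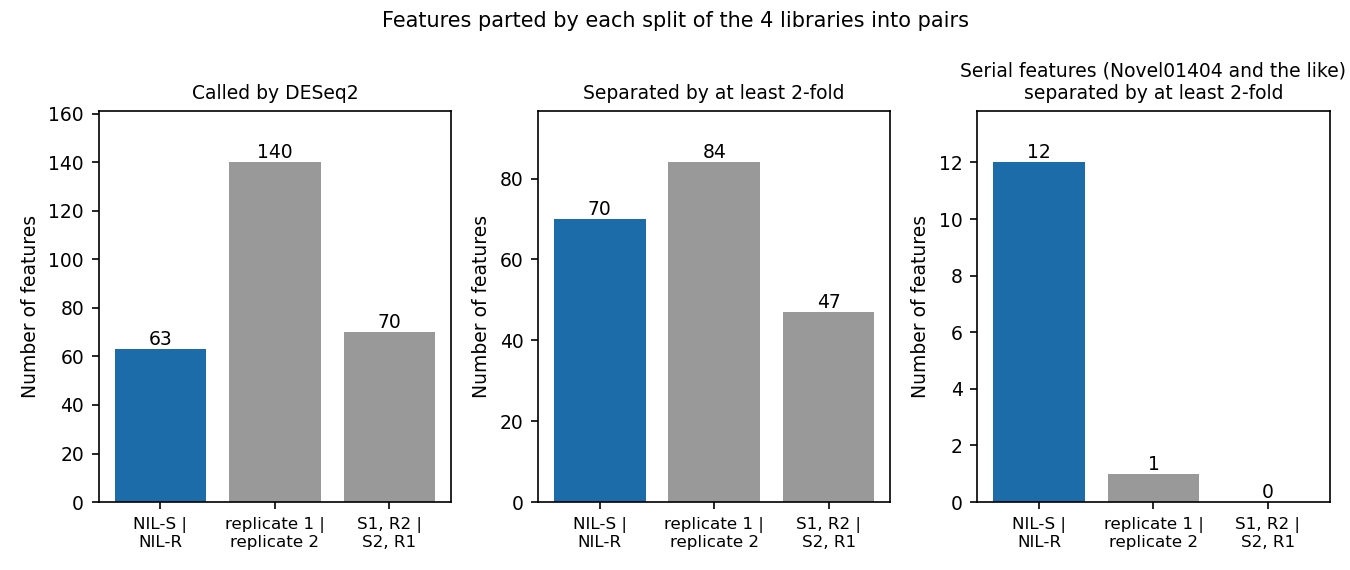
Number of features (vertical axes) called by DESeq2 at an adjusted p under 0.05, separated by at least 2-fold, and serial features among the separated, for the split by line (blue) and the 2 other splits of the 4 libraries (grey; S and R stand for NIL-S and NIL-R). The line split gave 63, 70 and 12, the split by replicate number 140, 84 and 1, and the remaining split 70, 47 and 0.

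MicroRNA genes were the features that could be given a name, and none of those tested differed detectably between the lines. Counts on these genes come from longer transcripts over the locus, not from the mature microRNA. Of 154 microRNA genes, 28 had counts and 8 passed the low-count filter and were tested. By edgeR's quasi-likelihood test 0 passed over all genes, 0 passed when adjusted over the list alone, and 0 had an unadjusted p under 0.05. DESeq2, edgeR's likelihood ratio test and limma-voom also called 0 of them. MIR399j and MIR399e belong to the phosphate starvation family miR399, which targets a ubiquitin-conjugating enzyme. MIR399j had 38.8 ± 5.0 CPM in NIL-S and 36.1 ± 0.96 in NIL-R (SD, n = 2 each). Its log2 fold change was -0.11, with a 95% interval of -0.44 to 0.23 that excludes a 2-fold change. MIR399e had 6.6 ± 1.3 CPM in NIL-S and 6.9 ± 0.85 in NIL-R (SD, n = 2 each), a log2 fold change of 0.06 (95% interval -0.52 to 0.63) that was -0.0030 when scaled by totals alone. MIR399c was counted at 18 and 17 in NIL-S and at 11 and 2 in NIL-R, with an interval of -3.40 to 0.40.

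MIR168a encodes miR168, which targets ARGONAUTE1, a core protein of antiviral RNA silencing. It had 37.9 ± 16.7 CPM in NIL-S and 29.8 ± 13.4 in NIL-R (SD, n = 2 each), a log2 fold change of -0.35 with a 95% interval of -1.64 to 0.95. The single libraries had 49.7 and 26.1 CPM in NIL-S and 39.3 and 20.3 CPM in NIL-R. MIR168b was low, with 16 and 13 counts in NIL-S and 12 and 8 in NIL-R. MIR408b belongs to a family that targets copper proteins and varied more within the lines than between them, with 5 and 69 counts in NIL-S and 116 and 8 in NIL-R. MIR156d and MIR156k, of the family that targets SPL transcription factors of phase change, had log2 fold changes of -0.07 (95% interval -1.08 to 0.94) and 0.41 (-0.74 to 1.56). MIR169n did not pass the low-count filter, with 6 and 6 in NIL-S and 7 and 40 in NIL-R. Near-identical family members can share reads, so values of single MIR168, MIR399 and MIR156 genes are uncertain.

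**Figure D2:**
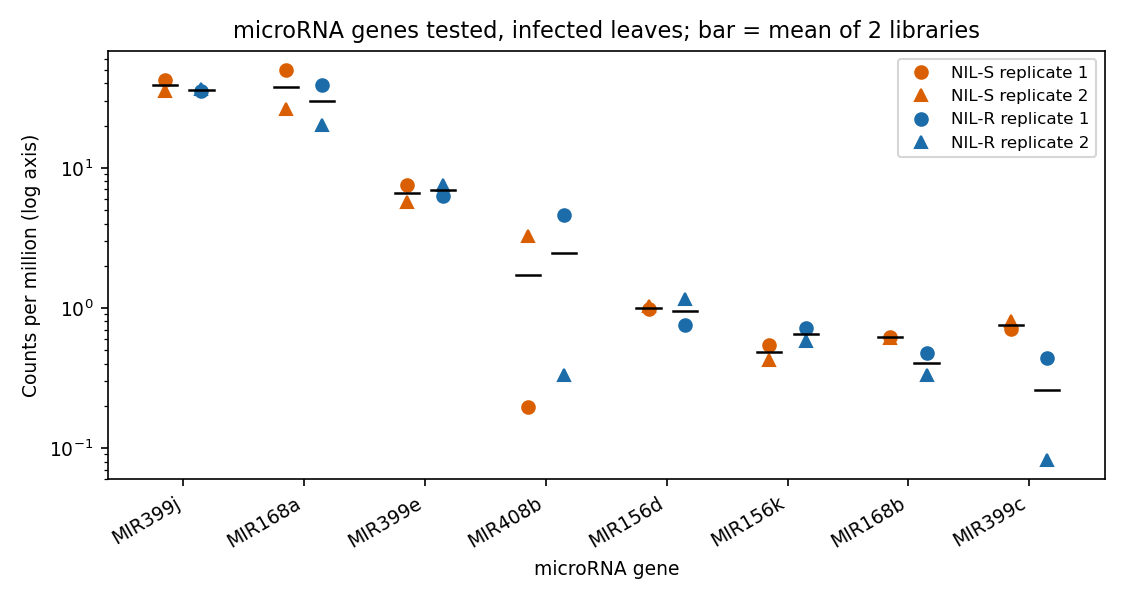
CPM on a log axis (vertical) of the 8 tested microRNA genes (horizontal) in each library of NIL-S (orange) and NIL-R (blue), with circles for replicate 1, triangles for replicate 2 and bars for the mean of 2 libraries. The lines overlap for MIR399j, MIR168a and MIR399e, and MIR408b spreads from 0.195 to 4.60 CPM across libraries of both lines.

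Some of the annotated genes with low p-values lay close together in identifier number. Of 22884 tested annotated genes, 149 had p under 0.01 by edgeR's quasi-likelihood test. Ordered by the number in the identifier, the fullest window of 50 consecutive tested genes held 9 of them, whereas random placement gave a median of 3 for the fullest window and a 95th percentile of 4 (permutation test, 100000 draws, one-sided p = 1e-05, the smallest these draws can give). Windows above that percentile formed 4 runs. The first, from number 10204 to 10422, held 14 low-p genes among 94 tested, 9 higher and 5 lower in NIL-R. The second, from 23243 to 23304, held 6 of 33, 5 higher and 1 lower. The third, from 28119 to 28229, held 8 of 58, 2 higher and 6 lower. The last, from 53603 to 53750, held 15 of 87, 9 higher and 6 lower.

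The 4 runs together held 1.19% of the tested annotated genes, 28.9% of those with p under 0.01 (43 of 149) and 23 of the 50 annotated genes called by DESeq2. The runs were chosen for low p-values in the same libraries, so neither the low-p genes nor the DESeq2 calls in them are separate support. The fullest window held 5 genes in the split by replicate number (permutation p = 0.438) and 4 in the remaining split (p = 0.312). Without NIL-R replicate 1 the fullest window held 8 genes, lay outside the 4 runs (numbers 21711 to 21798) and had a permutation p of 0.0552; without NIL-S replicate 1 it held 7 (p = 0.0384). With any library other than NIL-R replicate 1 left out, the fullest window lay at numbers 10189 to 10269 and overlapped the first run. The ordering by identifier number was chosen after the values were seen, and identifier numbers are not genome coordinates, which were not used here.

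**Figure D3:**
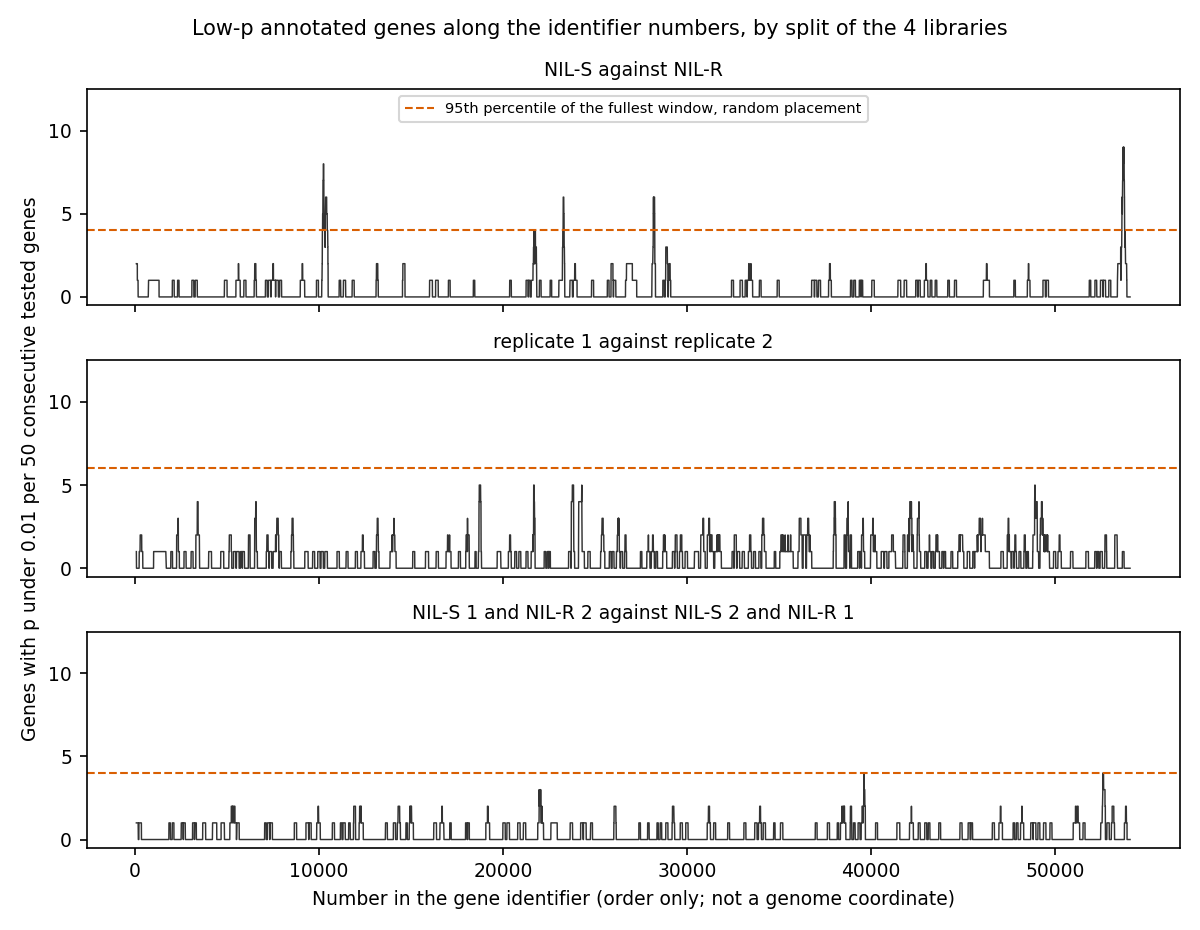
Number of annotated genes with p under 0.01 per 50 consecutive tested genes (vertical axis) along the number in the gene identifier (horizontal axis), for the split by line (top) and the 2 other splits of the 4 libraries. The dashed line is the 95th percentile of the fullest window under random placement; the split by line reaches 9 genes against 4, and the other splits reach 5 against 6 and 4 against 4.

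Pearson correlations of log2 CPM across genes were 0.963 between the NIL-S libraries and 0.974 between the NIL-R libraries, and the highest correlation of any pair, 0.977, was between NIL-S replicate 1 and NIL-R replicate 1. Genes are not independent replicates, so these correlations describe the libraries only. The 10 most counted features took 7.7% and 7.8% of the counts in NIL-S and 7.9% and 8.6% in NIL-R.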

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

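The DESeq2 fit with a block, the separated features and the identifier scan were chosen after the data were seen. The count of 0 genes differing between the lines held under limma-voom, RLE factors, totals alone, a minimum count of 50, all FPKM fits, the replicate block and each left-out library; a fold threshold on 0 calls can only give 0. It became 63 (40 higher, 23 lower) with DESeq2, 85 (52 and 33) with the likelihood ratio test, 11 (6 and 5) with no low-count filter, and 70 (50 and 20) with DESeq2 and a replicate block; the 11 were all among the DESeq2 calls, as were 42 of the 70; the cause was not tested. The 3 splits of the 4 libraries are too few for a share under 0.05; DESeq2 called 63 in the split by line and at most 140 in another (by replicate number). Deviations of same-numbered libraries correlated at 0.062, with 2 pairs only, so the numbers were not taken as pairs; edgeR with the replicate block called 0. The 70 separated features became 29 at a mean of at least 5 CPM (fewer features eligible) and 122 to 453 when 1 library was left out (fewer libraries to separate). The fullest identifier window held 7 to 8 genes when 1 library was left out, with the highest permutation p, 0.0552, without NIL-R replicate 1, where it lay outside the 4 runs; it passed under both other window widths, p under 0.001, DESeq2 calls and the replicate block. Fold changes of the 4 named identifiers kept their sign in all alternatives, but with 1 library left out ranged from -4.45 to -2.75 (log2) for Zm00001d039394 and -4.20 to -2.71 for Zm00001d028718; the fitted values of Zm00001d021770 (2.545 to 12.67 over all alternatives) and Novel01404 (2.82 to 12.55) depend on the prior count or pseudocount and were lowest in the FPKM fits with a pseudocount of 1. By DESeq2 with the replicate block, the adjusted p of Zm00001d021770 was 0.707, so its DESeq2 call was lost there, at a log2 fold change of 11.39 against 11.55 without the block, and the other 3 were called. Fold changes of 5 uncalled microRNA genes changed sign: with 1 library left out they ranged from -0.23 to 0.036 (MIR399j), -0.90 to 0.19 (MIR168a), -0.13 to 0.28 (MIR399e), -2.35 to 3.63 (MIR408b) and -0.41 to 0.20 (MIR156d), and MIR399e was -0.0030 with totals alone. A lone library is then assumed to vary like the other line. List tests and genome positions were not run, for want of gene names and coordinates. Of 28 microRNA genes with counts, 8 passed the low-count filter.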

Other observations

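All tests in this part were chosen after the result was seen. Of the 149 annotated genes with p under 0.01 between the lines, 43 (28.9%) fell in 4 runs of neighbouring identifier numbers, and the others lay outside them. Random placement gave a permutation p of 1e-05, the smallest the draws can give. A general tendency of neighbours to vary together between any libraries would also fill windows in the other 2 splits, whose fullest held 5 genes against 9. This argues against a general tendency, from 2 splits only. It does not bear on shared variation confined to the genes of the runs, because a line difference counts as spread in those splits. Poorer alignment of one line's reads in a run would lower its genes in that line, but 32.6% of the low-p genes (14 of 43) went against the direction of most in their own run. Poorer alignment in one line therefore does not account for all low-p genes of the runs. For the genes that went with the majority it stays open, and in the second run only 1 of 6 went against. That the runs are DNA segments that differ between the near-isogenic lines stays open, as a hypothesis. Among genes inside the runs that did not define them, 17.9% (41 of 229) had p under 0.05, against 3.1% (696 of 22506) outside, but the runs were chosen for low p-values in the same libraries, so such an excess follows from any local cause and does not tell the explanations apart. The hypothesis also rests on identifier numbers following the order of genes in the genome, which was not tested. Without NIL-R replicate 1 the fullest window lay outside the runs and the permutation p was 0.0552. Differences in alignment where both lines depart from the reference stay open too.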
